A study of Mus musculus with 10 samples.

How the data were processed

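Gene expression was measured in cells of peritoneal lavage from 10 female outbred CD1 mice on Affymetrix Mouse Gene 1.0 ST arrays, 1 array per mouse. Per the labels, 3 mice had been infected intraperitoneally with 500 tachyzoites of GT1, 2 with PTG and 3 with CTG, 2 were uninfected, and lavage was collected on day 5. The group of each array was taken from its label, and each array is named by its group and the mouse number in the label.

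The values analysed were the deposited log2 signals of the 10 arrays, between 2.52 and 14.86. Per the series' design text and the submitters' processing notes, the authors made them with robust multi-array averaging (RMA) in Partek software, which summarises the probes of a probe set and normalizes between arrays. The versions, the background and summary settings and the genome build were not given in the sources used here, and the log2 scale was read from the range of the values. No further normalization was applied. No 2 arrays held identical values. The median signal of the arrays over all probe sets lay between 5.45 and 5.70, and the number of arrays limited the precision.

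The table held 65535 probe sets at the level of single exons or small groups of probes. In the platform annotation 53709 of them named exactly 1 gene, 877 several and 10949 none, and only those with exactly 1 gene were used for named genes. Of 5040 symbols, 4328 were current, 699 were updated and 13 kept as given, using RefSeq gene names of assembly GRCm38.p6, which served only for names and chromosomes. Where a gene had several probe sets, the 1 with the highest mean over all 10 arrays was used, and the share of the other probe sets with the same sign was recorded. This left 5025 genes, with a median of 8 probe sets each and 547 genes with only 1. They made up 21.3% of the annotated protein-coding genes, and 98.3% of those with a chromosome lay on chromosomes 1, 10, 11, 12 and 13. Of the protein-coding genes, 88.7% were measured on chromosome 1, 88.3% on 10, 91.1% on 11, 83.9% on 12 and 72.7% on 13. Genes on other chromosomes were not analysed here, apart from a few probe sets annotated to them, for which a related copy on the 5 chromosomes cannot be excluded as the source of signal.

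Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 10 arrays, so that the 4 groups shared 1 estimate of the spread (6 residual degrees of freedom), and was followed by empirical Bayes moderation (3.25 prior degrees of freedom). The spread was not equal between groups, since CTG mouse 2 was noisier than the other arrays. Standard errors and p-values can therefore be too small for contrasts with CTG and too large for those of GT1 and PTG with uninfected mice. The 6 pairwise contrasts were tested with 2-sided moderated tests, and the 3 infected groups were compared with a moderated F test. P-values were adjusted by the Benjamini-Hochberg method over the 5025 genes of each contrast, with a threshold of 0.05 and no limit on fold change. A principal component analysis used centred values of all genes. All contrasts against uninfected mice share the same 2 arrays, so overlaps and correlations between contrasts were set beside 100 simulations of unchanged groups and beside the overlap of independent lists.

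Lists of genes were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over the lists of each contrast. The same test with the correlation estimated from the data and the rotation test fry were alternatives. Robust moderation used statmod 1.5.0. Of 29 lists, the 22 with at least 3 measured members were tested, a minimum set after the extent of the table was known. They covered interferon-gamma-inducible GTPases, other interferon-gamma-response genes, type I interferon-stimulated genes, parasite-restricting effectors, pro-inflammatory cytokines, chemokines, NF-kB targets, STAT6-responsive genes, immune-regulatory genes, glycolysis and hypoxia, cholesterol synthesis, oxidative phosphorylation, DNA replication and mitosis, and immediate-early and heat-shock genes. Cell type lists covered resident large peritoneal macrophages, inflammatory monocytes, neutrophils, B cells, T cells, NK and cytotoxic lymphocytes, dendritic cells, and mesothelial, stromal and adipose cells. The tested lists held 143 distinct genes, of which 3 (Ifng, Il12b and Batf3) were in more than 1 list. Cells that are not of the named type can also express a marker gene. The 7 lists with fewer measured members, listed with their values among the other observations, covered antigen presentation by MHC class I and class II, Toll-like receptors, complement, mast cells, eosinophils and erythroid cells.

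Genes named in the text were chosen by a fixed rule. For each contrast it takes the 6 genes with the largest increase and the 6 with the largest decrease among those past the threshold whose groups do not overlap, leaving out predicted gene models and olfactory and vomeronasal receptors. From each list past the camera test it takes up to 4 members past the threshold in the list's direction and up to 2 in the other, and from each other list the 1 or 2 members with the smallest adjusted p. In every contrast it takes a set of fixed genes, of which Irgm1, Igtp, Ifng, Nos2, Arg1, Il10 and Il12b were measured. For the F test it takes the 6 genes with the smallest p under the same limits of name and chromosome. About 20 to 30 of these genes are printed per main contrast. The groups, the tests, the lists, this rule and the other settings named in the next paragraphs were set before the data were examined. An exception is the limit of the rule to these chromosomes, which follows the extent of the table. Families of genes defined by their symbols were chosen after the values were seen and are described only among the other observations.

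The fit and the list test were tested on simulated data, in which 200 genes were changed by known amounts among the 5025 genes. The simulated arrays had the real gene means and, for each gene, the moderated estimate of spread, the same on every array. The extra noise of CTG mouse 2 was not simulated, so the shares recovered do not reflect differences in spread between groups. For GT1 against uninfected mice, 13.4%, 70.1% and 100% of genes changed by log2 differences of 1, 2 and 4 were recovered. The shares were 9%, 76.1% and 98.5% for PTG and 9%, 80.6% and 100% for CTG. In the same data a further list of 10 genes was raised by a log2 difference of 2 for the list test, and 8 of them were called in each comparison. Together 138, 136 and 143 genes were called in these 3 comparisons, of which 8, 6 and 9 had been changed in neither way.

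The other settings tried were moderation with trend and robust options, no moderation, leaving out genes below the 30th percentile of mean signal, quantile normalization, median centring, the mean of all probe sets of a gene, a fit of only the groups compared, a replicate block, array weights, all probe sets of the table, a threshold of 0.01, an estimated correlation, fry, and leaving out each array in turn. Resampling of genes for intervals used 500 draws. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.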

Results

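Cells washed from the peritoneal cavity of female outbred CD1 mice were profiled 5 days after intraperitoneal injection of 500 tachyzoites, the fast-dividing stage of the protozoan parasite Toxoplasma gondii. The strains were GT1, PTG and CTG, which per the series' design text belong to types I, II and III of the parasite. Each array held the RNA of 1 mouse, with 3 mice for GT1, 2 for PTG, 3 for CTG and 2 uninfected. The measured quantity was the log2 signal of probe sets on the Affymetrix Mouse Gene 1.0 ST array, and 5025 named genes were compared. These genes lay almost all on chromosomes 1, 10, 11, 12 and 13, so every list of genes below was measured in part. Median signals of the 10 arrays over all probe sets lay between 5.45 and 5.70. The number of arrays limited the precision, with a median standard error of 0.36 for GT1 and CTG and 0.39 for PTG against uninfected mice. These errors rest on a spread shared by the 4 groups, although arrays correlated at 0.870 to 0.962 within CTG and 0.962 to 0.977 within GT1. They can thus be too small for CTG and too large for GT1 and PTG. No detection call was used here. For groups with a mean signal under 5.70, the highest of these medians, differences are given as log2 signal and not as folds, a limit set after the values were seen, because the size of a change is uncertain at such low signal. Levels are given as mean log2 signal ± SD, and differences as log2 ± standard error (SE) with the adjusted p of limma's moderated test. The naming rule picked 207 gene differences past the threshold, of which only some are printed. In each of the 207, no array of either group overlapped the other group.

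Along the first principal component of the gene signals, which held 37.0% of the variance, the uninfected, CTG and other infected mice lay apart, while GT1 and PTG mice overlapped. The uninfected mice lay at 41.4 and 44.6, the CTG mice at 4.4, 31.0 and 7.1, the PTG mice at −26.9 and −27.6, and the GT1 mice at −22.1, −23.1 and −28.9. On the third component, with 9.3% of the variance, PTG mice at −21.4 and −16.7 lay apart from GT1 mice at 10.4, 7.4 and −0.1. CTG mouse 2 stood apart from all other arrays on the second component, which held 26.9% of the variance, with a score of 65.9. Its correlation across genes with the other 9 arrays was 0.828 to 0.887, while the 2 PTG arrays correlated at 0.983. Lists whose camera call changed without this array, and genes that lost their call without it, are given as such where they are named for a comparison. Counts of list members past the test could also move without it.

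**Figure D1:**
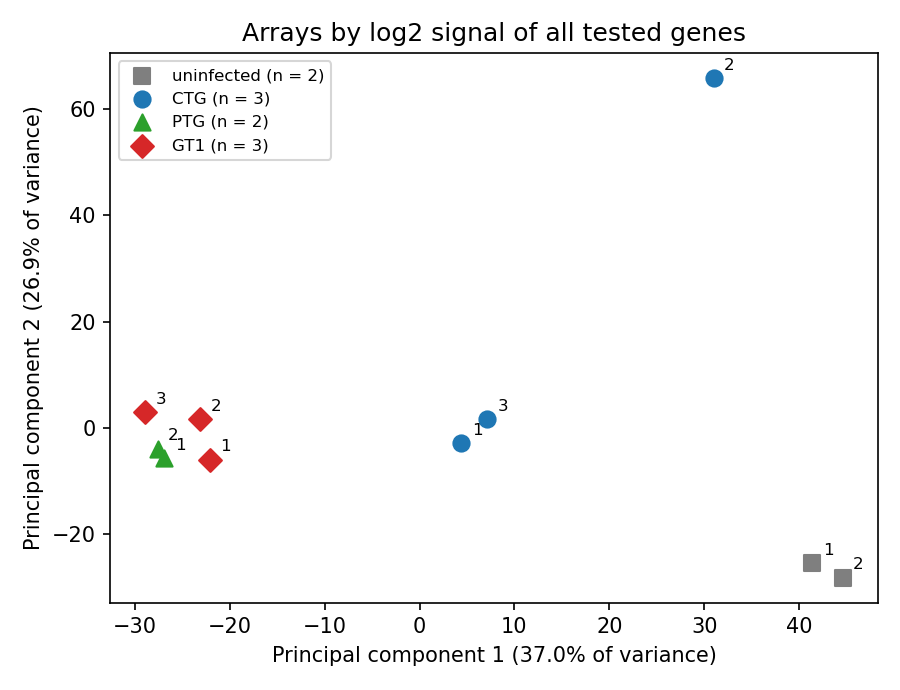
Each point is 1 array, placed by its scores on the first (x axis, 37.0% of variance) and second (y axis, 26.9%) principal components of the log2 signals of 5025 genes, with colour and marker for the group. Uninfected mice lie at the right, GT1 and PTG mice together at the left, and CTG mouse 2 alone at the top.

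In mice infected with GT1, genes of the interferon-gamma response and chemokine genes rose over uninfected mice, as did single T cell and cytotoxic genes such as Cd28 and Prf1, and markers of the resident peritoneal macrophage fell. Ifng, which encodes interferon-gamma itself, stood at 10.95 ± 0.88 (SD, n = 3) with GT1 and 4.22 ± 0.32 (SD, n = 2) in uninfected mice, a difference of 6.73 ± 0.48 (adjusted p = 8.18e-05). Upp1, the pyrimidine-salvage enzyme uridine phosphorylase 1, rose by 7.71 ± 0.43 from 4.00 ± 0.96 to 11.71 ± 0.28. The chemokine gene Ccl3 rose by 7.68 ± 0.41 from 4.27 ± 0.11 to 11.95 ± 0.40, and the neutrophil chemokine receptor gene Cxcr2 by 6.62 ± 0.78 from 4.69 ± 0.32 to 11.31 ± 0.53. Serpinb10, a clade B serpin, fell by 7.33 ± 0.49 from 11.97 ± 0.22 to 4.64 ± 0.86, and Prg4, which encodes the lubricating proteoglycan lubricin, fell by 6.95 ± 0.56 to 5.20 ± 1.18. In all, 367 genes were higher and 251 lower with GT1 at an adjusted p below 0.05.

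All 5 measured interferon-gamma-inducible GTPases rose with GT1 (5 adjusted over the list alone; camera adjusted p = 1.19e-09). Irgm1 rose 17.3-fold from 8.00 ± 0.06 to 12.11 ± 0.31, Igtp 20.3-fold, Gm12250 25.2-fold and Ifi47 15.5-fold. Of 4 other interferon-gamma-response genes 3 rose (4 adjusted over the list alone; camera adjusted p = 6.53e-06), among them the transcription factor gene Irf1 at 3.29 ± 0.31 and Slamf8 at 5.30 ± 0.58. All 6 type I interferon-stimulated genes rose (6 adjusted over the list alone; camera adjusted p = 5.75e-08), with the antiviral gene Rsad2 at 5.52 ± 0.46 and Dhx58 at 4.45 ± 0.39. Chemokines rose at 9 of 15 members, with 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.19e-07). The monocyte attractant gene Ccl2 rose by 6.43 ± 0.66 to 11.38 ± 0.70 and its neighbour Ccl12 by 5.97 ± 0.46 to 10.14 ± 0.67. Immune-regulatory genes rose at 7 of 8 members (8 adjusted over the list alone; camera adjusted p = 1.22e-07), including Il1r2, the decoy receptor for interleukin-1, at 5.15 ± 0.52 and Pdcd1, the inhibitory receptor PD-1, at 4.14 ± 0.49. Il10, whose product restrains inflammation, was at 6.74 ± 0.89 against 5.52 ± 0.03, short of the threshold over all genes (adjusted p = 0.129). These 5 lists also passed the test with an estimated correlation between genes.

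With GT1, of 8 pro-inflammatory cytokines 3 rose (3 adjusted over the list alone), namely Ifng, Il12b, a subunit of interleukin-12, at 5.40 ± 0.59, and the growth factor gene Csf2 at 3.89 ± 0.44 (1.87 as the median over its 5 probe sets). The list passed at an adjusted p of 0.0231, against an adjusted p = 0.0782 with an estimated correlation and 0.0544 without CTG mouse 2. NF-kB target genes rose at 5 of 9 members (6 adjusted over the list alone; camera adjusted p = 7.21e-06, and adjusted p = 0.0623 with an estimated correlation), with Tnfaip2 at 3.33 ± 0.47 and Tnfaip3, an inhibitor of the same pathway, at 2.86 ± 0.50. Of 5 STAT6-responsive genes of alternative activation 4 rose (4 adjusted over the list alone; camera adjusted p = 0.00048, and adjusted p = 0.0965 with an estimated correlation). Among them Arg1, arginase 1, rose by 3.29 ± 0.77 from 8.87 ± 0.11 to 13.2, 12.92 and 10.39 in the 3 mice, and Egr2 rose by 2.53 ± 0.25. Socs2 was also counted there, although only 3 of its 8 probe sets had that sign. Effector enzymes and transporters that restrict parasites rose at 2 of 4 members (3 adjusted over the list alone; camera adjusted p = 0.0083, and adjusted p = 0.0623 with an estimated correlation), the metal transporters Slc40a1 at 4.51 ± 0.83 and Slc11a1 at 1.77 ± 0.35. Nos2, the inducible nitric oxide synthase, was at 10.39 ± 0.56 against 8.00 ± 0.04, with an adjusted p of 0.0625 over all arrays and 0.00603 without CTG mouse 2.

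Marker genes of cell types also moved with GT1. Resident large peritoneal macrophage markers fell at 8 of 9 members (9 adjusted over the list alone) with a median difference of −4.68 (camera adjusted p = 6.61e-10), among them Serpinb2 at −6.22 ± 0.56, Tgfb2 at −6.07 ± 0.44 and the lipoxygenase gene Alox15 at −4.85 ± 0.96. Inflammatory monocyte markers rose at 3 of 4 members (3 adjusted over the list alone; camera adjusted p = 0.000987), including the Fc receptor gene Fcgr4 at 3.17 ± 0.24. Ifi204, also a gene of the interferon-inducible p200 family, rose by 3.74, but by 0.76 as the median over its 5 probe sets. F13a1 did not rise, at 11.04 ± 0.56 against 10.73 ± 0.44 in uninfected mice. Both the resident macrophage and the monocyte list passed with an estimated correlation. T cell markers rose at 5 of 7 members (7 adjusted over the list alone; camera adjusted p = 1.95e-06, and adjusted p = 0.0665 with an estimated correlation), with Cd28 at 3.74 ± 0.50 and Icos at 3.04 ± 0.43. NK and cytotoxic lymphocyte markers rose at 4 of 5 members, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00309, and adjusted p = 0.166 with an estimated correlation). The perforin gene Prf1 rose by 5.80 ± 0.93 and the Fas ligand gene Fasl by 4.03 ± 0.54. Of 3 neutrophil markers only Cxcr2 rose (2 adjusted over the list alone; camera adjusted p = 0.014, and adjusted p = 0.0691 with an estimated correlation). B cell markers fell at 2 of 8 members (5 adjusted over the list alone; camera adjusted p = 0.00396, and adjusted p = 0.242 with an estimated correlation), Ebf1 at −1.94 ± 0.34 and Cd79b at −1.58 ± 0.40. Dendritic cell markers held 1 gene that rose and 1 that fell among 4, Itgae at 2.04 ± 0.52 (0.72 as the median over its 32 probe sets) and Irf4 at −1.85 ± 0.50 (1 each adjusted over the list alone; camera adjusted p = 0.775). Of 7 mesothelial, stromal and adipocyte markers 0 passed limma's test over all genes or the list alone (camera adjusted p = 0.279).

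DNA replication and mitosis genes rose at 8 of 10 members with GT1 (9 adjusted over the list alone; camera adjusted p = 3.04e-08, and adjusted p = 0.0623 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose 41.3-fold to 11.22 ± 0.23, and the topoisomerase gene Top2a rose to 12.08 ± 0.27, from 9.04 and 7.52 in the 2 uninfected mice. Glycolysis and hypoxia genes rose at 6 of 9 members (7 adjusted over the list alone; camera adjusted p = 1.95e-06, past also with an estimated correlation). They included the lactate transporter gene Slc16a3 at 3.50 ± 0.44, the hexokinase gene Hk1 at 2.66 ± 0.42 (0.91 as the median over its 25 probe sets) and Hif1a, a subunit of the hypoxia-inducible factor, at 2.18 ± 0.44. Of 7 mitochondrial oxidative phosphorylation genes Atp5b alone rose, at 1.09 ± 0.24 (1 adjusted over the list alone; camera adjusted p = 0.0875). Of 3 cholesterol synthesis genes and of 6 immediate-early and heat-shock genes, 0 passed limma's test over all genes or the list alone (camera adjusted p = 0.184 and 0.252). The total of 618 genes became 1052 without CTG mouse 2, and 273, 314, 349 and 389 without uninfected mouse 2, uninfected mouse 1, GT1 mouse 2 and GT1 mouse 3. The mean over all probe sets of a gene gave 964 genes.

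**Figure D2:**
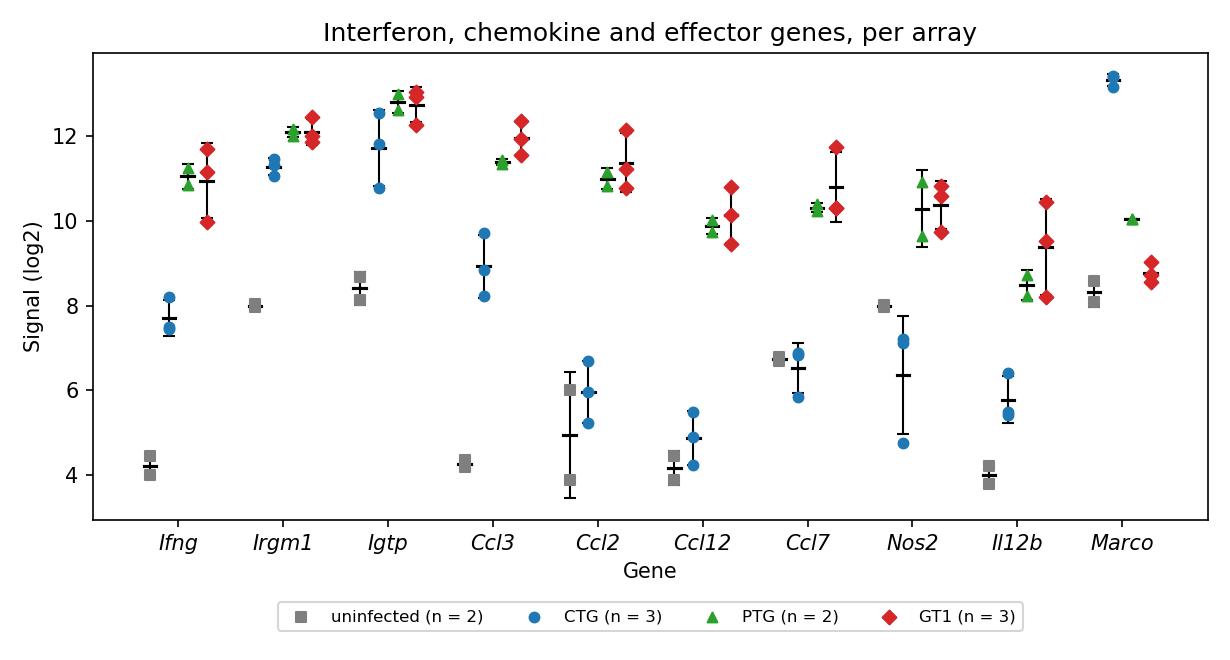
Log2 signal (y axis) of the response genes named on the x axis in the 4 groups, with 1 point per array and the bar and its error showing the mean and SD. Ifng stood at 10.95 with GT1, 11.05 with PTG, 7.72 with CTG and 4.22 in uninfected mice.

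Infection with PTG raised and lowered many of the genes named for GT1. Upp1 rose by 7.83 ± 0.47 to 11.83 ± 0.26 (SD, n = 2), Ccl3 by 7.12 ± 0.45 to 11.39 ± 0.07 and Ifng by 6.83 ± 0.52 to 11.05 ± 0.29. Prf1 rose by 6.17 ± 1.02 to 11.04 ± 0.59, Ccl2 by 6.05 ± 0.72 and Cxcr2 by 5.97 ± 0.85. Genes with large falls in signal were Serpinb10 at −6.93 ± 0.54, Alox15 at −6.45 ± 1.05, Prg4 at −5.69 ± 0.61, Tgfb2 at −5.03 ± 0.49 and Selp, the adhesion molecule P-selectin, at −5.02 ± 0.64. Tppp, a tubulin-binding protein gene, fell by 4.99 ± 0.61. In all, 347 genes were higher and 240 lower than in uninfected mice at an adjusted p below 0.05, and quantile normalization of the arrays gave 305 higher and 328 lower.

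The interferon lists rose with PTG as well. All 5 GTPases passed (5 adjusted over the list alone; camera adjusted p = 1.38e-08, and adjusted p = 0.0528 with an estimated correlation), with Irgm1 at 12.09 ± 0.11, 17.1-fold above uninfected mice, and Igtp 21.1-fold above them. Other interferon-gamma-response genes rose at 3 of 4 members (4 adjusted over the list alone; camera adjusted p = 2.21e-05) and type I interferon-stimulated genes at 6 of 6 (6 adjusted over the list alone; camera adjusted p = 2.55e-07), with Rsad2 at 5.44 ± 0.50. Chemokines rose at 10 of 15 members (10 adjusted over the list alone; camera adjusted p = 6.62e-08), with Ccl12 at 5.71 ± 0.50 and Ccl8 at 5.53 ± 1.28. Ccl11 among them had that sign at only 3 of its 5 probe sets. Immune-regulatory genes rose at 5 of 8 (6 adjusted over the list alone; camera adjusted p = 4.28e-05), with Il1r2 at 4.02 ± 0.57 and Socs3, an inhibitor of cytokine signalling, at 2.61 ± 0.46 (1.25 as the median over its 4 probe sets). These 4 lists also passed with an estimated correlation. Il12b rose by 4.49 ± 0.65 to 8.48 ± 0.35 and Arg1 11.9-fold to 12.45 ± 0.51, while Il10 was at 6.42 ± 0.19 with an adjusted p of 0.293. Nos2 was at 10.29 ± 0.90, with an adjusted p of 0.0929 over all arrays and 0.0117 without CTG mouse 2.

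NF-kB target genes rose at 6 of 9 members with PTG (7 adjusted over the list alone; camera adjusted p = 0.000108, and adjusted p = 0.0938 with an estimated correlation), among them the cyclooxygenase gene Ptgs2 at 1.81 ± 0.42 and Tnfaip2 at 3.08 ± 0.51. Parasite-restricting effectors rose at 2 of 4 (3 adjusted over the list alone; camera adjusted p = 0.00729, and adjusted p = 0.0669 with an estimated correlation). Pro-inflammatory cytokines rose at 3 of 8, with 3 higher and 1 lower adjusted over the list alone, at an adjusted p of 0.0361 (adjusted p = 0.0994 with an estimated correlation, and 0.0835 without CTG mouse 2). STAT6-responsive genes rose at 3 of 5 (3 adjusted over the list alone) at an adjusted p of 0.0354 (adjusted p = 0.296 with an estimated correlation, and 0.0784 without CTG mouse 2). Among them Socs2 had that sign at only 4 of its 8 probe sets. DNA replication genes rose at 6 of 10 (9 adjusted over the list alone; camera adjusted p = 4.07e-06, and adjusted p = 0.0994 with an estimated correlation), with Rrm2 at 4.88 ± 0.60. Glycolysis genes rose at 5 of 9 (5 adjusted over the list alone; camera adjusted p = 0.000203, and adjusted p = 0.0564 with an estimated correlation), with Slc16a3 at 3.19 ± 0.48 and Hif1a at 2.49 ± 0.48.

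Resident macrophage markers fell at 8 of 9 members with PTG (8 adjusted over the list alone), with a median of −4.29 (camera adjusted p = 1.7e-09, and adjusted p = 0.0528 with an estimated correlation). Inflammatory monocyte markers rose at 3 of 4 (3 adjusted over the list alone; camera adjusted p = 0.00246, and adjusted p = 0.0528 with an estimated correlation), with the orphan receptor gene Gpr141 at 5.49 ± 0.81 and Ifi204 at 4.72 ± 1.07 (2.21 as the median over its 5 probe sets). F13a1 did not rise, at 10.47 ± 0.11 against 10.73 ± 0.44 in uninfected mice. T cell markers rose at 4 of 7 (5 adjusted over the list alone; camera adjusted p = 4.79e-05, and adjusted p = 0.0994 with an estimated correlation), and NK and cytotoxic markers at 4 of 5, with 1 lower adjusted over the list alone (camera adjusted p = 0.0048, and adjusted p = 0.205 with an estimated correlation). The interleukin-18 receptor gene Il18rap rose by 5.09 ± 0.91 and Cd28 by 3.29 ± 0.55. Cxcr2 was the only neutrophil marker of 3 to rise (1 adjusted over the list alone; camera adjusted p = 0.0199, and adjusted p = 0.0938 with an estimated correlation). Of 8 B cell markers Ebf1 alone fell, at −1.50 ± 0.37 (1 adjusted over the list alone; camera adjusted p = 0.0199, and adjusted p = 0.322 with an estimated correlation). The total of 587 genes became 1132 without CTG mouse 2, and 140, 168, 203 and 325 without PTG mouse 1, PTG mouse 2, uninfected mouse 2 and uninfected mouse 1. A fit of the PTG and uninfected arrays alone gave 927 genes.

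With CTG, interferon-responsive genes such as Irgm1 and the cytotoxic lymphocyte gene Prf1 rose over uninfected mice while none of the 9 resident macrophage markers passed limma's test. Cd7, a surface protein of T and NK cells, rose 36.5-fold from 5.72 ± 0.12 (SD, n = 2) to 10.91 ± 0.47 (SD, n = 3). Marco, the macrophage scavenger receptor, rose 32-fold from 8.33 ± 0.36 to 13.33 ± 0.14. Ccl3 rose by 4.66 ± 0.41 to 8.93 ± 0.75, Prf1 by 4.48 ± 0.93 to 9.35 ± 0.52 and Rrm2 by 4.29 ± 0.55 to 10.14 ± 1.17. Cd247, the zeta chain of the T cell receptor, rose by 4.30 ± 0.42, although the median over its 14 probe sets was 0.91. Genes with large falls in signal were the small GTPase gene Diras2 at −4.48 ± 0.82 (−1.42 as the median over its 3 probe sets), Tppp at −3.90 ± 0.56, Rgs13, a regulator of G-protein signalling, at −3.77 ± 0.41, and Prkar2b, a regulatory subunit of protein kinase A, at −3.56 ± 0.47. In all, 221 genes were higher and 76 lower at an adjusted p below 0.05.

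Ifng rose by 3.50 ± 0.48 with CTG to 7.72 ± 0.42, Irgm1 9.71-fold to 11.28 ± 0.20 and Igtp 9.9-fold to 11.72 ± 0.89. All 5 GTPases rose (5 adjusted over the list alone; camera adjusted p = 2.55e-09, and adjusted p = 0.0898 with an estimated correlation). Other interferon-gamma-response genes rose at 3 of 4 (3 adjusted over the list alone; camera adjusted p = 0.000179, and adjusted p = 0.0652 with an estimated correlation), with Irf1 at 2.91 ± 0.31. Type I interferon-stimulated genes rose at 4 of 6 (6 adjusted over the list alone; camera adjusted p = 1.09e-06, and adjusted p = 0.0632 with an estimated correlation), with Rsad2 at 4.11 ± 0.46. Chemokines rose at 3 of 15 (5 adjusted over the list alone; camera adjusted p = 0.00373, and adjusted p = 0.0898 with an estimated correlation), namely Ccl3, the T cell attractant gene Ccl5 at 4.17 ± 0.39, and Xcl1 at 2.19 ± 0.52. Immune-regulatory genes rose at 3 of 8 (4 adjusted over the list alone; camera adjusted p = 0.00379, and adjusted p = 0.11 with an estimated correlation). Of these Pdcd1 rose by 2.17 ± 0.49 (0.64 as the median over its 6 probe sets), with an adjusted p of 0.0374 over all arrays and 0.0567 without CTG mouse 2. The signals of Il12b at 5.78 ± 0.56, Arg1 at 11.36 ± 0.71, Il10 at 6.21 ± 0.41 and Nos2 at 6.37 ± 1.39 did not differ from uninfected mice past the threshold (adjusted p = 0.115, 0.0949, 0.43 and 0.217).

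DNA replication genes rose at 5 of 10 members with CTG (9 adjusted over the list alone; camera adjusted p = 2.51e-06, and adjusted p = 0.161 with an estimated correlation). Glycolysis genes rose at 3 of 9 (4 adjusted over the list alone; camera adjusted p = 0.00145, and adjusted p = 0.11 with an estimated correlation), Hk1 at 3.16 ± 0.42 (1.11 as the median over its probe sets), Slc16a3 at 2.83 ± 0.44 and Hk3 at 1.53 ± 0.29. T cell markers rose at 4 of 7 (5 adjusted over the list alone; camera adjusted p = 0.000131, and adjusted p = 0.172 with an estimated correlation), including Icos at 1.88 ± 0.43, whose adjusted p of 0.0396 became 0.0586 without CTG mouse 2. NK and cytotoxic markers rose at 3 of 5 (4 adjusted over the list alone; camera adjusted p = 0.00355, and adjusted p = 0.217 with an estimated correlation), with Fasl at 3.10 ± 0.54 (1.44 as the median over its 11 probe sets) and Tbx21, a transcription factor gene of interferon-gamma-producing lymphocytes, at 3.30 ± 0.74. The adjusted p of Tbx21 moved from 0.0339 to 0.0513 without CTG mouse 2. B cell markers fell at 1 of 8 (2 adjusted over the list alone; camera adjusted p = 0.0155, and adjusted p = 0.336 with an estimated correlation), Ebf1 at −1.49 ± 0.34 (adjusted p = 0.0374, and 0.0504 without CTG mouse 2).

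The remaining lists did not pass the camera test with CTG. Resident macrophage markers had a median difference of 0.69 with 0 of 9 members past limma's test over all genes or the list alone (camera adjusted p = 0.0738). Prg4 was at 13.23 ± 0.17 against 12.15 ± 0.06 in uninfected mice, and Icam2, an adhesion molecule of these macrophages, at 11.35 ± 0.71 against 10.20 ± 0.23. Inflammatory monocyte markers rose at 2 of 4, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.067, and 0.0424 without CTG mouse 2), and Fcgr4 rose 16.8-fold to 12.69 ± 0.10. The lower member was F13a1, at 7.48 ± 2.09 against 10.73 ± 0.44 in uninfected mice. Cxcr2 rose by 3.64 ± 0.78 as 1 of 3 neutrophil markers (camera adjusted p = 0.11). The total of 297 genes became 91, 113, 153, 153 and 160 without uninfected mouse 2, uninfected mouse 1, PTG mouse 1, PTG mouse 2 and GT1 mouse 2. A fit of the CTG and uninfected arrays alone gave 62 genes.

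**Figure D3:**
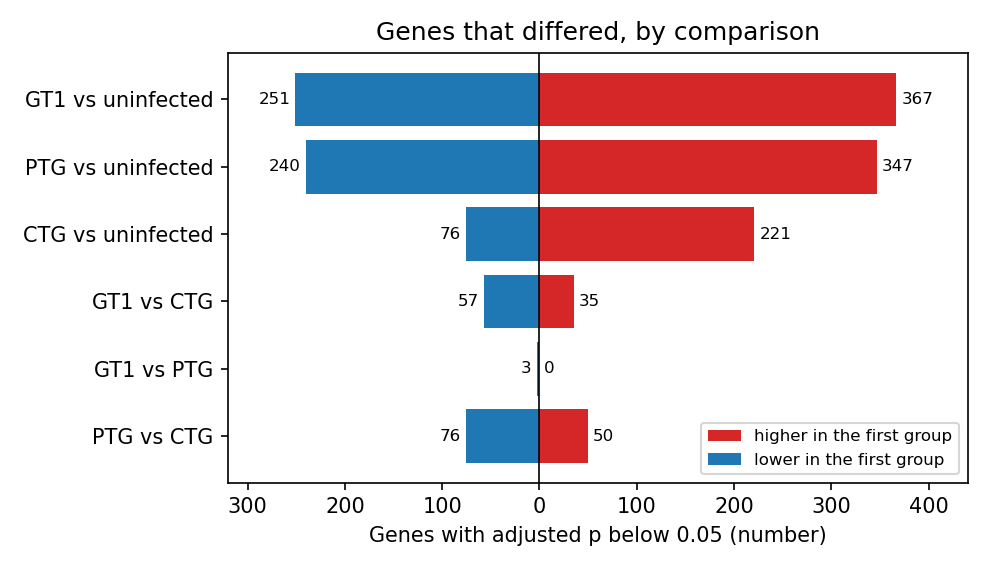
Number of genes (x axis) with an adjusted p below 0.05 in each comparison (y axis), with bars to the right for genes higher and to the left for genes lower in the group named first. The bars run from 367 higher and 251 lower for GT1 against uninfected mice to 0 higher and 3 lower for GT1 against PTG.

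Set against CTG directly, GT1 gave higher signals of monocyte-attracting chemokines, Nos2 and Il12b and far lower signals of resident macrophage markers. Ccl2 was 42.6-fold higher at 11.38 ± 0.70 against 5.97 ± 0.74 (SD, n = 3 each), Ccl12 higher by 5.26 ± 0.41 and Ccl7 19.3-fold higher. Nos2 was higher by 4.02 ± 0.64 (adjusted p = 0.0129), and by 3.22 ± 0.42 without CTG mouse 2. Il12b was at 9.53, 8.2 and 10.46 against 5.78 ± 0.56, higher by 3.61 ± 0.53 (adjusted p = 0.00746), and Rgs1, a regulator of G-protein signalling, was higher by 3.57 ± 0.36. Prg4 was at 5.20 ± 1.18 against 13.23 ± 0.17, a difference of −8.04 ± 0.50, and Serpinb10 and Tgfb2 differed by −6.49 ± 0.44 and −6.28 ± 0.40. Serpinb2 and Selp were lower by factors of 111 and 44.9. Aspa, the enzyme aspartoacylase, was at 4.89 ± 0.78 against 10.54 ± 0.26, a difference of −5.65 ± 0.37. In all, 35 genes were higher and 57 lower with GT1. Of the 35, 31 were also called higher against uninfected mice with GT1 and 4 with CTG, and of the 57, 41 were called lower with GT1 and 9 higher with CTG.

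All 9 resident macrophage markers were lower with GT1 than with CTG (9 adjusted over the list alone), at a median difference of −5.11 (camera adjusted p = 1.73e-19), and 8 were without CTG mouse 2. Chemokines were higher at 5 of 15 members, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.11e-05), including Ccl3 at 3.02 ± 0.37. Immune-regulatory genes were higher at 2 of 8 (6 adjusted over the list alone; camera adjusted p = 3.9e-06), Il1r2 at 3.47 ± 0.47 and the inhibitory receptor gene Havcr2 at 2.69 ± 0.53. These 3 lists passed with an estimated correlation, and the other 11 lists past the camera test did not. NF-kB target genes were higher at 2 of 9 (5 adjusted over the list alone; camera adjusted p = 3.8e-07, and adjusted p = 0.0626 with an estimated correlation), Il12b and Cd83, a maturation marker of antigen-presenting cells, at 2.00 ± 0.36. Egr2 was higher by 1.69 ± 0.23 among 5 STAT6-responsive genes (2 adjusted over the list alone; camera adjusted p = 0.000453, and adjusted p = 0.132 with an estimated correlation). Ifng was higher by 3.23 ± 0.43 (adjusted p = 0.00469) as 1 of 4 interferon-gamma-response genes (1 adjusted over the list alone; camera adjusted p = 0.00207, and adjusted p = 0.0626 with an estimated correlation). The GTPases passed the camera test at 0.00318 (1 adjusted over the list alone; adjusted p = 0.194 with an estimated correlation) with 0 of 5 past limma's test over all genes. Irgm1 differed by 0.83 ± 0.23 and Igtp by 1.03 ± 0.43 (adjusted p = 0.137 and 0.357). Nos2 was the 1 effector of 4 past the test, and that list's adjusted p moved from 0.0427 to 0.07 without CTG mouse 2 (adjusted p = 0.132 with an estimated correlation). Arg1 and Il10 did not differ past the threshold, at 0.81 ± 0.69 and 0.53 ± 0.42 (adjusted p = 0.616 and 0.594).

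Of the other lists past the camera test between GT1 and CTG, cytokines were higher at 2 of 8 members (2 adjusted over the list alone; camera adjusted p = 0.0192, and adjusted p = 0.117 with an estimated correlation). Glycolysis genes were higher at 1 of 9, Pgk1, which is annotated to chromosome X, outside those covered, and at 0 by limma without CTG mouse 2 (2 adjusted over the list alone; camera adjusted p = 0.00318, and adjusted p = 0.117 with an estimated correlation). Type I interferon-stimulated genes (1 adjusted over the list alone; camera adjusted p = 0.0048), DNA replication genes (0; 0.00318), T cell markers (0; 0.00516) and neutrophil markers (1; 0.0408) had 0 members past limma's test over all genes. Their p with an estimated correlation was an adjusted p = 0.117, 0.229, 0.213 and 0.132. B cell markers had a median difference of −0.53 with 0 of 8 past the test (camera adjusted p = 0.237). The total of 92 genes became 57 without GT1 mouse 2, 46 in a fit of the GT1 and CTG arrays alone and 315 with the mean over all probe sets of a gene.

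**Figure D4:**
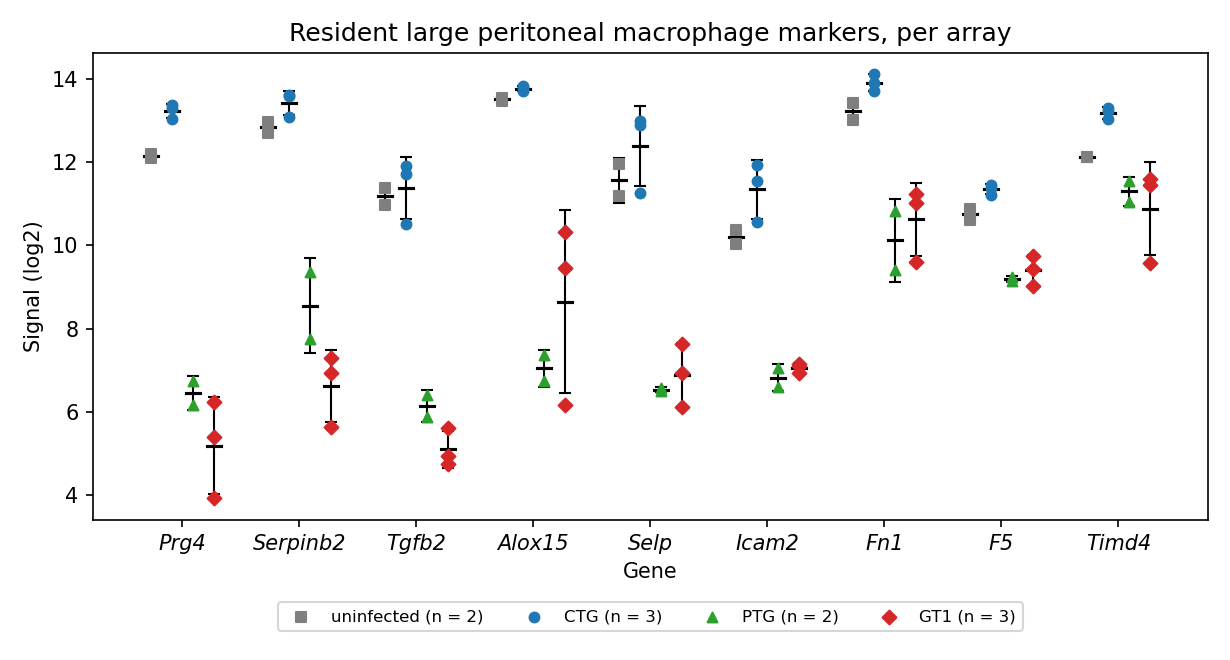
Log2 signal (y axis) of the resident macrophage genes named on the x axis in the 4 groups, with 1 point per array and the bar and its error showing the mean and SD. Prg4 stood at 5.20 with GT1, 6.46 with PTG, 13.23 with CTG and 12.15 in uninfected mice.

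PTG differed from CTG in many of the same ways. Ccl12 was higher by 5.01 ± 0.46, at 9.88 ± 0.18 (SD, n = 2) against 4.88 ± 0.63 (SD, n = 3), Ccl2 32.6-fold, Ccl7 13.9-fold and Upp1 12-fold. Nos2 was higher by 3.93 ± 0.72 (adjusted p = 0.026), and by 3.12 ± 0.46 without CTG mouse 2, with the 2 PTG mice at 10.93 and 9.65. Ccl11, an eosinophil attractant gene, was higher by 3.42 ± 0.30 at the probe set used, but only 2 of its 5 probe sets had that sign and their median was −0.00. Prg4 was lower by a factor of 109, Alox15 by 105 at 7.05 ± 0.43 against 13.76 ± 0.07, Selp by 57.1 and Tgfb2 by 37.8, while Serpinb10 and Aspa differed by −6.09 ± 0.49 and −5.64 ± 0.41. In all, 50 genes were higher and 76 lower with PTG, of which 42 and 47 were also called in that direction for PTG against uninfected mice. The comparisons of GT1 and PTG with CTG shared 20 genes higher and 42 lower, against 0.35 and 0.86 for independent lists. No gene was called in opposite directions. The count was 0 in 100 simulations in which all arrays, CTG ones included, were drawn with no difference between groups. Few genes are called in such data, so that 0 does not measure what the shared CTG arrays add. Across genes the covariance of the log2 differences was 0.45, against 0.08 in those simulations. They gave every array the same spread for a gene, without the extra noise of CTG mouse 2. Part of the overlap may come from the shared CTG arrays.

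Resident macrophage markers were lower with PTG than with CTG at 8 of 9 members (9 adjusted over the list alone), at a median of −4.87 (camera adjusted p = 1.49e-15, and adjusted p = 0.055 with an estimated correlation). Chemokines were higher at 5 of 15, with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.2e-05, and adjusted p = 0.055 with an estimated correlation). Ifng was higher by 3.33 ± 0.48 (adjusted p = 0.00799) as 1 of 4 interferon-gamma-response genes (1 adjusted over the list alone; camera adjusted p = 0.028, and adjusted p = 0.193 with an estimated correlation). Il12b was higher by 2.70 ± 0.59 as 1 of 9 NF-kB target genes (5 adjusted over the list alone; camera adjusted p = 8.65e-05, and adjusted p = 0.193 with an estimated correlation), with an adjusted p of 0.0499 over all arrays and 0.0776 without CTG mouse 2. Type I interferon-stimulated genes had 0 of 6 past limma's test over all genes or the list alone, and that list's adjusted p of 0.028 became 0.0706 without CTG mouse 2 (adjusted p = 0.196 with an estimated correlation). Immune-regulatory genes had 0 of 8 past (2 adjusted over the list alone), and their adjusted p of 0.0487 became 0.0864 without CTG mouse 2 (adjusted p = 0.212 with an estimated correlation). Hif1a was higher by 2.03 ± 0.44 (adjusted p = 0.0493). Irgm1, Igtp, Arg1 and Il10 did not differ past the threshold, at 0.82 ± 0.26, 1.09 ± 0.48, 1.09 ± 0.77 and 0.21 ± 0.46 (adjusted p = 0.138, 0.267, 0.482 and 0.843). The 6 lists past the camera test became 3 without CTG mouse 3, and the total of 126 genes became 16, 23 and 78 without PTG mouse 1, PTG mouse 2 and GT1 mouse 2. It was 34 in a fit of the PTG and CTG arrays alone and 313 with the mean over all probe sets.

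GT1 and PTG differed in 3 genes, all lower with GT1, out of 5025 tested by limma, while 510 had an unadjusted p below 0.05. Ccl11 was at 4.73 ± 0.06 (SD, n = 3) with GT1 and 7.76 ± 0.34 (SD, n = 2) with PTG (adjusted p = 0.0127), Mettl23, a methyltransferase-like gene, at 6.91 ± 0.11 and 9.25 ± 0.34 (adjusted p = 0.041), and Stum at 5.45 ± 0.24 and 7.52 ± 0.11 (adjusted p = 0.0347). The median over all probe sets of these genes was far smaller, at −0.31 for Ccl11, −0.37 for Mettl23 and −0.17 for Stum. Ifng differed by −0.10 ± 0.48, Irgm1 by 0.01 ± 0.26, Igtp by −0.06 ± 0.48, Nos2 by 0.10 ± 0.72, Arg1 by −0.28 ± 0.77, Il10 by 0.32 ± 0.46 and Il12b by 0.91 ± 0.59, with no adjusted p under 0.71. Resident macrophage markers had a median of 0.19 and a mean of −0.20 with 0 of 9 past limma's test over all genes or the list alone (camera adjusted p = 0.788). STAT6-responsive, immune-regulatory and dendritic cell lists were each higher with GT1 at a camera adjusted p of 0.0336 with 0 members past limma's test over all genes (1, 1 and 0 adjusted over the list alone). They were past neither with an estimated correlation (adjusted p = 0.887, 0.448 and 0.415) nor without CTG mouse 2 (0.0925, 0.0866 and 0.0753). The 3 genes became 20 without CTG mouse 2, 1 without CTG mouse 1, CTG mouse 3 or either uninfected mouse, and 0 without any of the GT1 or PTG mice. Array weights, which gave CTG mouse 2 a weight of 0.16, raised the count to 501, and leaving out dim genes lowered it to 0.

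Tested together, the 3 strains differed in 124 genes by limma's moderated F test at an adjusted p below 0.05. The genes with the smallest p were Marco (adjusted p = 9.71e-05), Aspa, Prg4 and Tgfb2 (0.000157 each), Serpinb10 (0.000168) and Ccl12 (0.000336). Marco was at 8.77 ± 0.24 with GT1, 10.05 ± 0.01 with PTG and 13.33 ± 0.14 with CTG. Aspa was at 4.89 ± 0.78 with GT1 and 4.90 ± 0.08 with PTG, below 8.34 ± 0.27 in uninfected mice, and at 10.54 ± 0.26 with CTG, above them. The 124 genes became 48, 59 and 69 without PTG mouse 1, PTG mouse 2 and GT1 mouse 2, and 345 with the mean over all probe sets.

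A response common to the 3 strains was counted as genes called in the same direction in each infection against uninfected mice. It held 156 higher and 48 lower genes, against 1.11 and 0.18 for independent lists. Irgm1, Igtp, Ifng, Ccl3, Rsad2, Cd28 and Rrm2 were among the higher, and Tppp, Diras2, Rgs13 and Prkar2b among the lower genes. The count was 0 in 100 simulations in which all arrays, uninfected ones included, were drawn with no difference between groups. Few genes are called in such data, so that 0 does not measure what the shared controls add. Across genes, the log2 differences of GT1 and PTG had a correlation of 0.87 and a covariance of 0.99, against 0.55 and 0.12 in the simulation. The correlation was 0.73 for GT1 and CTG and 0.66 for PTG and CTG, closer to the 0.6 and 0.55 of the simulation. The covariance was 0.66 for GT1 and CTG and 0.62 for PTG and CTG, against 0.12 and 0.11. GT1 and PTG shared 262 higher and 151 lower genes (25.3 and 12 for independent lists), GT1 and CTG 186 and 60 (16.1 and 3.8), and PTG and CTG 164 and 50 (15.3 and 3.6). The simulated values include the sharing of controls, but with the same spread on every array. The 2 uninfected arrays were not split between the comparisons, so part of each excess may come from the shared controls. The 204 common genes became 68, 70, 78, 92 and 116 without uninfected mouse 2, PTG mouse 1, PTG mouse 2, uninfected mouse 1 and GT1 mouse 2.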

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

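The tests of dilution, of loss of cells and of dim signals were chosen only after the results were seen, and the other tests in this part were set earlier.

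Aspa was picked out because its response went in opposite directions in the strains. It fell by 3.46 and 3.45 (log2) with GT1 and PTG and rose by 2.20 with CTG relative to uninfected mice, all past the threshold. The direct differences, tested with limma, were −5.65 for GT1 against CTG and −5.64 for PTG against CTG, with adjusted p-values of 8.49e-05 and 0.000496. All 8 probe sets of Aspa had these signs. Ackr3, which lay outside the naming rule and was noticed after its values were seen, differed in the same way by −1.64 with GT1 and 2.26 with CTG, and by −1.33 with PTG without passing the threshold (adjusted p = 0.058). No explanation was tested for either gene.

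Probe sets with no gene in the annotation take no part in the comparisons of genes, and a signal appeared among them. Of 10949 such probe sets, 98 were higher in all 3 infections than in uninfected mice and 262 lower, whereas of the 53709 probe sets with exactly 1 gene 548 were higher and 281 lower. The mean over probe sets with no gene was 5.80 and 5.75 on the uninfected arrays and 5.45 to 5.66 on the others. A general rise of dim signals on the uninfected arrays would place dim named genes lower in the infected groups, but the median difference over 1508 dim named genes was −0.06, 0.05 and 0.11 for GT1, PTG and CTG, which argues against it. What these probe sets measure was not tested, and no biological explanation was tested.

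CTG mouse 2 stood apart from every other array, and its array weight was 0.16. Noise of single probe sets may account for much of this: the deviation of that array from the other CTG arrays had an intraclass correlation of 0.03 (95% interval over resampled genes 0.02 to 0.05) among probe sets of the same gene, against 0.11 to 0.49 for the other arrays, with a SD of 1.58 against 0.52 to 1.11. This was measured on 26760 of the brighter probe sets in 2565 genes. A compressed signal range was argued against as the main source, since a smooth function of the signal level explained 6% of the variance of the deviation (5 to 7.1). A small compression beside this noise cannot be excluded. The slope of CTG mouse 2 on the mean of the other CTG arrays was 0.89, although noise in those arrays also lowers a slope. A weaker response to infection in that mouse was also argued against as the main source, since the deviation had a correlation of 0.02 (−0.01 to 0.04) with the response. The correlation was −0.1 when computed as first written, with shared arrays, and the form without shared arrays was adopted later. A weaker response hidden by the noise cannot be excluded. On the first principal component this mouse lay at 31.0, nearer the uninfected mice at 41.4 and 44.6 than the other CTG mice at 4.4 and 7.1.

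Resident macrophage markers were far lower with GT1 and PTG than with CTG. Dilution of all resident cells by incoming cells would lower the B cell markers alike if B cells neither entered nor expanded, which was not tested. With GT1 and PTG mice pooled, the resident macrophage list fell by 4.48 more than the B cell list (a difference of −4.48, with −5.34 to −3.62 spanning 2 standard errors on each side). Dim members of the B cell list, such as Vpreb3 with group means of 5.21 to 6.26, could hardly fall. Under that assumption on B cells, the difference argues against dilution alone. A favourable choice of probe sets was argued against, since 99.4% of the 155 probe sets of these 9 genes were lower with GT1 than with CTG. Loss of the cells and lower expression per cell cannot be told apart, because the 9 genes fell by amounts with a SD of 2.06 that either could give when other cells also express some of them. The pattern is itself a difference between strains, which the direct comparisons above tested. What in the strains or the infections brings it about was not tested.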

How the results depend on the processing

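All alternatives were planned except the minimum of 3 members per list and the families, which were chosen after the data were seen. The 207 differences picked by the naming rule gave 3409 calls kept, 515 weaker and 0 reversed among 3924 repeats. Most of these repeats could not reverse a sign. Changes of moderation, of the genes tested or of the groups fitted leave the log2 difference as it was. Leaving out or weighting arrays cannot flip it where the groups do not overlap. Only quantile normalization, median centring, the mean of all probe sets and the replicate block could. Over all called genes signs changed only with the mean of all probe sets (24 of 618 genes for GT1, 34 of 587 for PTG, 6 of 297 for CTG against uninfected mice and 4 of 126 for PTG against CTG). Counts moved more, and except where fewer genes or arrays were used the cause was not tested. Trend and robust moderation gave 7 genes and 1 list for GT1 against PTG. No moderation gave 158 (CTG against uninfected), 37 (GT1 against CTG), 6 (GT1 against PTG), 38 (PTG against CTG) and 50 (F test). For GT1 against PTG, leaving out dim genes gave 0, quantile normalization 1 gene and 0 lists, and median centring 1. The mean of all probe sets gave 964 (GT1), 517 (CTG), 315 (GT1 against CTG), 5, 313 (PTG against CTG), 345 (F), 315 common genes and 10 lists (PTG against CTG). Fits of only the groups compared gave 927 (PTG), 62 (CTG), 46, 7 and 34 (PTG against CTG). Array weights gave 982 (GT1), 1163 (PTG), 501 genes and 0 lists (GT1 against PTG), 307 and 546 (F). All probe sets gave 4506, 3738, 2128, 781, 11, 958 and 905 in the order GT1, PTG and CTG against uninfected, GT1 against CTG, GT1 against PTG, PTG against CTG and F test, and an adjusted p under 0.01 gave 255, 191, 87, 47, 0, 39 and 50. An estimated correlation left 8, 4, 0, 3, 0 and 0 lists in the same order, and fry 0 for GT1 against PTG. The replicate block gave 194 (CTG), 0 (GT1 against PTG), 80 (F) and 133 common genes. Whether the mouse numbers pair the samples was not settled. Over 13 pairs with the same number the deviations correlated at −0.128 to 0.335, with 2 pairs above 0.1. Over 24 pairs with different numbers they correlated at −0.203 to 0.185, with 7 above 0.1. The highest value, 0.335, was that of GT1 mouse 1 with CTG mouse 1. In groups of 2 mice the deviations mirror each other, so pairs with those groups tell little. Leaving out each array gave 273 to 1052 (GT1), 140 to 1132 (PTG), 91 to 398 (CTG), 57 to 114 (GT1 against CTG), 0 to 20 (GT1 against PTG), 16 to 159 (PTG against CTG), 48 to 172 (F) and 68 to 301 common genes, and 16 to 17, 14 to 17, 9 to 12, 11 to 17, 0 to 4 and 3 to 7 lists in that order of comparisons. The lowest counts came without uninfected mouse 2 (GT1, CTG, common genes), PTG mouse 1 (PTG, PTG against CTG, F) and GT1 mouse 2 (GT1 against CTG), and the highest count for GT1 and PTG came without CTG mouse 2; where 1 array of a group was left, it was assumed to vary like the other groups. Dim probe sets near the lowest signals limit what can be seen of small changes.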

Other observations

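The gene families in this part were chosen after the values were seen, and the lists and the splits of the samples were set earlier.

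Some genes of the p200 and Schlafen families rose in all 3 infections. Of 5 measured genes of the interferon-inducible p200 family, which includes sensors of DNA, 4 rose with GT1, 4 with PTG and 3 with CTG. The median differences were 1.93, 2.67 and 1.76. The DNA sensor gene Aim2 did not pass limma's test in any infection, at −0.38, 0.02 and −0.14 (adjusted p = 0.333, 0.972 and 0.755). Ifi205 rose by 3.50, 4.38 and 3.04 (adjusted p = 0.000894, 0.000754 and 0.0037) and Ifi202b by 1.93, 2.67 and 1.76. Of 8 Schlafen genes, which include regulators of T cell growth, 4, 4 and 3 rose, and Slfn1 rose by 3.84 ± 0.23, 4.08 ± 0.25 and 3.53 ± 0.23. Among 5 genes of the interleukin-1 and interleukin-18 receptor family, Il1r2, Il18r1 and Il18rap rose with GT1 and PTG, and 0 of the 5 passed limma's test with CTG. Il18r1 differed by 4.23, 4.49 and 2.75 (adjusted p = 0.0225, 0.0277 and 0.138). Between GT1 and CTG directly, Il1r2 differed by 3.47, while Il18r1 (1.48) and Il18rap (1.22) did not pass. The directions of these medians were the same with quantile normalization and median centring. Camera with its preset correlation gave an adjusted p of 0.00364, 0.000368 and 0.00356 for the p200 family, 1.33e-06, 1.22e-05 and 0.000608 for the Schlafen family and 0.0172, 0.00406 and 0.132 for the receptor family. With an estimated correlation the p200 family had an adjusted p = 0.143, 0.146 and 0.283, the Schlafen family an adjusted p = 0.143, 0.147 and 0.291, and the receptor family an adjusted p = 0.227, 0.149 and 0.31. The camera calls thus depend on the correlation assumed. Because the families were chosen after their values were seen, these p-values are descriptive at either setting and are not a test. Of 31 histone genes of chromosome 13, 12, 7 and 7 rose, but near-identical copies make the single genes uncertain.

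Clade B serpins, intracellular protease inhibitors, moved in opposite directions within 1 family. Of 24 measured, 3 rose and 5 fell with GT1, and 3 rose and 7 fell with PTG. Serpinb9, which inhibits granzyme B, rose by 4.07 ± 0.65 with GT1 and 4.76 ± 0.71 with PTG, with Serpinb9b and Serpinb9e, while Serpinb10, Serpinb2, Serpinb1a, Serpinb6a and Serpinb8 fell with both. With CTG, Serpinb7 rose by 2.15 (adjusted p = 0.0486) and 0 fell by limma's test. These counts with CTG were 3 and 1 without CTG mouse 2 and 0 and 0 by limma with quantile normalization, and without that mouse 7 fell with GT1 and 10 with PTG. In the direct comparison 6 serpins were lower with GT1 than with CTG, as were 6 with PTG. The median of the family with CTG was 0.04 and became −0.09 with quantile normalization, so it has no settled sign. As a family not linked to immune cells, 27 keratins had 0 higher and 3 lower genes with GT1.

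Other genes that set CTG apart lay outside the naming rule and were noticed after their values were seen. Pmp22 was at 7.21 ± 0.52 with GT1, 7.15 ± 0.47 with PTG, 11.57 ± 0.34 with CTG and 10.93 ± 0.45 in uninfected mice. Nrp2 was at 10.15 ± 0.21, 10.33 ± 0.54, 7.07 ± 0.27 and 6.41 ± 0.16, and Edn1, which encodes endothelin-1, at 8.09 ± 0.55, 7.71 ± 0.10, 4.64 ± 0.56 and 4.45 ± 0.51. Each differed between CTG and both other strains by limma, with adjusted p-values against GT1 of 0.000227 for Pmp22, 0.000379 for Nrp2 and 0.00131 for Edn1, and 3 of 3 GT1 arrays lay on the same side. In contrast Slc6a4, the serotonin transporter, was lower in all 3 infections, at 6.63 ± 0.30, 7.26 ± 0.01 and 7.01 ± 0.05 against 9.23 ± 0.01, and Igf1 was at 6.67 ± 0.66, 6.65 ± 0.07 and 7.87 ± 0.60 against 9.81 ± 0.40.

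The lists too small to be tested held few measured genes. The mast cell gene Fcer1a differed from uninfected mice by −3.59 ± 0.60 with GT1 (adjusted p = 0.0054), −1.94 with PTG and −1.76 with CTG, and Lilr4b by 2.43, 3.19 and −0.05, past the threshold with PTG (adjusted p = 0.0333). Of complement genes, Cd55 differed by −1.51 ± 0.34 with GT1 (adjusted p = 0.0187), −0.87 and −0.50, and Cfd by 0.78, 0.71 and 0.44. The eosinophil gene Epx and the erythroid genes Slc4a1 and Sptb did not pass limma's test in any infection. The same held for Irak3 and Ly96 of the list of Toll-like receptors and adaptors and for Erap1 of the list of MHC class I antigen presentation. In those lists no Toll-like receptor itself and no class I molecule itself was measured, and 0 genes of the MHC class II list were measured.

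The number of genes that differed between GT1 and CTG was set against other divisions of the 6 mice into 3 and 3. Of 10 splits, 1, the real one, gave as many genes, with 92 against a highest other of 0, and 1 gave as many lists past the camera test, with 14 against a highest other of 7. With 10 splits there are too few for a share under 0.05.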
